A study of Phaseolus vulgaris with 18 samples.

How the data were processed

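The series measured gene expression by RNA sequencing in grain and pod of the common bean, Phaseolus vulgaris, at 10, 15 and 20 DAF, read here as days after flowering because the labels do not spell the term out. Each of the 6 groups held 3 libraries, 18 in all. Per the labels' protocols, total RNA was extracted with TRIzol and 1 µg of it went into each library, made with a SMARTER mRNA kit. The design text of the series speaks of 4 periods, whereas the labels give 3 stages, and the labels were followed. They do not say whether the 3 libraries of a group came from separate plants, so p-values measure only the spread between these samples, which may be technical.

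The authors deposited their values as TPM, a measure of transcript abundance scaled within each library, in 1 table of 27420 genes by 18 libraries, with a description of the best Arabidopsis-style match for each gene. No description was given for 4644 genes. The aligner, the counting tool, the handling of reads shared between similar genes and the genome build are not given in the sources used here. TPM keeps no read depth, so the depth of each library is unknown and no counting interval was computed. Similarity between gene copies was not measured here, so it is open how far reads shared within families such as the cupins, lectins or histones affect the value of a single gene. The gene table used as a reference shared no identifiers with the expression table, so genes are named by the deposited identifiers and descriptions and no coordinates are given.

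Columns were matched to samples by tissue, stage and number. The pod 10 DAF titles are numbered 3, 4 and 5 and their columns 1, 2 and 3, so those columns were assigned to the group without a replicate number and are called c1, c2 and c3. Values were used as deposited, on the log2(TPM + 1) scale, for the 19861 genes with at least 1 TPM in at least 3 libraries. A fold on this scale understates the change of a gene with low values. All comparisons came from 1 limma fit with 6 group means, empirical Bayes moderation with an intensity trend and 12 residual degrees of freedom. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 and a log2 difference of at least 1 in size. The difference between tissues in the change from 10 to 20 DAF was tested as an interaction in the same fit.

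Gene lists were search patterns on the deposited descriptions. The test, the filter, the thresholds, the other settings to be tried, the rule for named genes and 31 lists were set before the data were examined. A further 18 lists were worded after the descriptions, but no expression values, had been read, because several of the first patterns matched few genes or genes of other kinds. In the Results these are the cupin, core histone, cell cycle and replication, ribosomal protein, light-harvesting and secondary wall lists. The seed maturation regulator, wider abscisic acid, lipoxygenase and aquaporin lists were worded then too. The 45 lists with at least 5 kept members were tested with the camera test of limma at a preset correlation of 0.01 and again with an estimated correlation, 2-sided, with Benjamini-Hochberg adjustment over the lists of a comparison. Camera compares a list with all other genes. An exact permutation test of 3 against 3 libraries cannot go below p = 0.1, so the summed TPM of lists is given with its SD and without a test.

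Genes were named by 3 rules. In the comparisons of 20 with 10 DAF within a tissue, and of grain with pod at 10 and at 20 DAF, the rule took the 6 largest called differences each way among described genes with at least 20 TPM in the higher group and no overlap between the libraries of the groups. In the other comparisons it took 2 each way. It also took the 3 most abundant members of each list, and for each list the called member with the largest difference each way with at least 5 TPM.

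The other settings fixed beforehand were a pseudocount of 0.1 TPM, no filter, a filter at 5 TPM, median-ratio scaling, leaving out the 50 most abundant genes and rescaling, a fit on only the groups compared, no intensity trend, no minimum difference, a replicate block and each library left out in turn. Median-ratio scaling divided each library by its median ratio to the geometric mean over 11276 genes above 1 TPM in every library. It removes most of any general shift by construction, so a small median over all genes after it says nothing about such a shift. Rescaling each column to the same sum, and leaving out libraries in the list tests, were added after the data had been seen. The steps were tested on simulated data built from the means and spreads of the real genes. In a simulation of grain at 20 against 10 DAF over 19565 genes, 41 of 100 genes changed by a log2 of 1.5 were recovered and 100 of 100 changed by a log2 of 3, none with the wrong sign, beside 12 false calls. Of 45 unchanged lists, 1 was called by camera, and a planted list of 20 genes had an adjusted p of 2.06e-23. The simulated noise was independent between genes, and as many genes were raised as lowered. The simulation therefore did not cover lists of correlated genes or a shift of most genes. Tools were R 4.3.3, limma 3.58.1, Python 3.11.15 and matplotlib 3.10.9.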

Results

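Grain and pod of the common bean were compared at 10, 15 and 20 days after flowering (DAF), with 3 libraries in each of 6 groups. Values below are the mean ± SD in TPM with n = 3 libraries, log2 differences carry the standard error (SE) of the fit, and adjusted p-values are from limma. The libraries of a group correlated at r = 0.905 to 0.981 across genes, libraries of 1 tissue at different stages at r = 0.748 to 0.968, and a grain with a pod library at r = 0.591 to 0.747. Of the 18 libraries, 2 correlated better with another stage than with their own group. Pod 10 DAF c2 was closest to pod 15 DAF replicate 3 (r = 0.938, against 0.926 and 0.929 in its group) and grain 20 DAF replicate 3 to grain 15 DAF replicate 1 (r = 0.968, against 0.947 and 0.958). These r describe libraries, since genes are not independent replicates. The 50 most abundant genes of a library took 15.4% to 17.2% of its TPM in grain at 10 DAF, 49.9% to 60.2% at 15 DAF and 58.4% to 72.8% at 20 DAF, against 17.8% to 26.1% in pods. The deposited values of pod 15 DAF replicate 3 summed to 436072 TPM, and those of the other 17 libraries to between 823001 and 999633 TPM. The depth of the libraries is unknown.

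In grain, cupin, LEA, oil body and raffinose transcripts rose in sum from 10 to 20 DAF. All 8 genes whose descriptions name the seed storage cupins PAP85 or CRA1, called cupin genes below, rose, and their summed level went from 1214 ± 1059 to 119098 ± 16534 TPM. Their list was worded after the descriptions were read. Of 23 genes of late embryogenesis abundant (LEA) proteins, which accumulate in drying seeds, 19 rose and 3 fell, and after median-ratio scaling 20 rose and 0 fell. LEA4-5 (Phvul.001G142000) stood at 8.80 ± 5.14 TPM at 10 DAF and 11946 ± 6540 TPM at 20 DAF (log2 difference 10.25, SE 0.72, adjusted p = 5.42e-09). Oil body proteins, which coat the oil droplets of seeds, rose in 5 of 12 genes and fell in 3, or 7 and 1 after median-ratio scaling. The oleosins Phvul.007G138300 and Phvul.008G144500 went from 352 ± 149 to 3890 ± 553 TPM and from 175 ± 68.3 to 2941 ± 325 TPM. Of 7 genes for raffinose family sugars 4 rose and 2 fell, led by galactinol synthase 1 (Phvul.001G215300) from 1.71 ± 1.39 to 109 ± 27.5 TPM. Of 6 abscisic acid genes 2 rose and 1 fell, or 5 and 0 after median-ratio scaling, and the bZIP factor ABI5 (Phvul.007G229600) rose from 6.0 ± 2.3 to 90.6 ± 61.3 TPM. A wider abscisic acid list of 37 genes, worded after the descriptions were read, had 4 that rose and 14 that fell, or 12 and 3 after median-ratio scaling. Its median of -0.57 and mean of -0.33 were negative, while the camera test passed upwards at adjusted p = 0.000114, with adjusted p = 0.593 with an estimated correlation. Of 10 seed maturation regulators, also worded after the descriptions were read, 2 rose and 5 fell, or 4 and 4 after median-ratio scaling. The sum over 12 matched genes went from 1829.8 ± 402 to 1319.5 ± 134 TPM, but from 1400.1 ± 320 to 2529 ± 616 after median-ratio scaling. Their median of -1.59 and mean of -0.72 were negative, while the camera test pointed upwards without passing, at adjusted p = 0.262 and, with an estimated correlation, 0.664. The cupin, LEA, oil body, raffinose and 6-gene abscisic acid lists passed the camera test upwards, with adjusted p from 6.76e-42 for LEA to 6.39e-05 for abscisic acid. They also passed with an estimated correlation, at adjusted p = 0.00711 to 0.0245. Adjusted over the list alone, the LEA, oil body, raffinose and abscisic acid counts were 19 and 3, 5 and 3, 4 and 2, and 2 and 1. Among the single genes with the largest rises, a Rossmann-fold protein (Phvul.003G091300) went from 2.51 ± 2.48 to 2678 ± 324 TPM and a potato type I inhibitor (Phvul.005G032000) from 3.20 ± 2.41 to 2553 ± 1239 TPM. The legume lectin-like gene Phvul.004G158000 went from 157 ± 239 to 17442 ± 4309 TPM. The defensin-like PDF2.3 (Phvul.005G071300) was at 23413, 962 and 227 TPM in the 3 libraries at 20 DAF, against 4.98 ± 2.85 TPM at 10 DAF.

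Photosynthesis, chromatin, cell division and ribosome transcripts fell in grain over the same days. None of 77 photosynthesis genes rose and 64 fell, 64 also when adjusted over the list alone, and the sum over all 85 matched genes went from 8516 ± 1212 to 457 ± 251 TPM. The antenna protein gene LHCB3 (Phvul.005G085800) fell from 219 ± 40.6 to 1.17 ± 1.17 TPM, and 28 of 34 light-harvesting genes fell. Of 46 core histone genes 44 fell and 1 rose, and the centromeric histone CENH3 (Phvul.010G112000) went from 148 ± 36.6 to 3.28 ± 3.54 TPM. Of 49 cell cycle and replication genes 44 fell, including the mitotic kinase CDKB2;2 (Phvul.001G000500) from 368 ± 139 to 9.83 ± 15.1 TPM. Ribosomal protein genes fell in 266 of 289 cases, and after median-ratio scaling 151 fell and 4 rose. Of these 5 lists, all but photosynthesis were worded after the descriptions were read. The 5 lists passed the camera test downwards, with adjusted p from 9.62e-12 for ribosomal proteins to 7.14e-05 for light-harvesting proteins. None passed with an estimated correlation, at adjusted p = 0.40 to 0.691. The largest single falls were those of the purine permease PUP4 (Phvul.009G245400), from 595 ± 112 to 0.30 ± 0.32 TPM (log2 difference -8.85, SE 0.42, adjusted p = 3.69e-11). Others were those of a cell wall protein precursor (Phvul.005G106200), from 385 ± 33.0 to 0.0653 ± 0.0615 TPM, and an acid phosphatase (Phvul.010G144200), from 1183 ± 274 to 3.49 ± 3.74 TPM. KLU (Phvul.003G041200), a cytochrome P450 that promotes organ growth in Arabidopsis, fell from 447 ± 101 to 1.31 ± 0.872 TPM. The transcription factor SPL4 (Phvul.006G183900) fell from 903 ± 330 to 4.31 ± 2.57 TPM. Of 13 starch synthesis genes 2 rose and 3 fell, with the same counts when adjusted over the list alone. Their median and mean log2 differences were -0.29 and -0.40 while the camera test pointed upwards, at adjusted p = 0.0230. That value became 0.691 with an estimated correlation, 0.0583 with no filter and 0.0786 without grain 10 DAF replicate 1. Of 20 protease inhibitor genes 4 rose and 7 fell, 4 and 7 also when adjusted over the list alone. Their median was -0.06 and their mean 0.11, and the camera test pointed upwards at adjusted p = 7.14e-05 (adjusted p = 0.203 with an estimated correlation). The list for the words of seed storage proteins took 61 genes described mostly as members of a superfamily shared by lipid-transfer proteins and 2S albumins. Of these, 3 rose and 31 fell, or 2 and 31 when adjusted over the list alone. Its camera test gave an adjusted p of 0.607, 0.00712 downwards after median-ratio scaling and 0.0223 with the 50 most abundant genes left out. The member Phvul.003G169100 fell from 1090 ± 370 to 18.4 ± 14.1 TPM.

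In all, 530 genes were higher and 10516 lower in grain at 20 than at 10 DAF, and the median log2 difference of all genes tested was -1.08. Median-ratio scaling, which removes most of such a shift by construction, took that median to -0.11 and gave 1665 higher and 3313 lower genes. Relative to that shift the cupin median was a log2 of 8.87 in place of 7.57 and the LEA median 5.71 in place of 4.42. The photosynthesis median was -2.71 in place of -3.50, the core histone median -2.26 in place of -3.39 and the ribosomal median -1.08 in place of -2.33. With the 50 most abundant genes left out, 1425 genes were higher and 4037 lower.

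**Figure D1:**
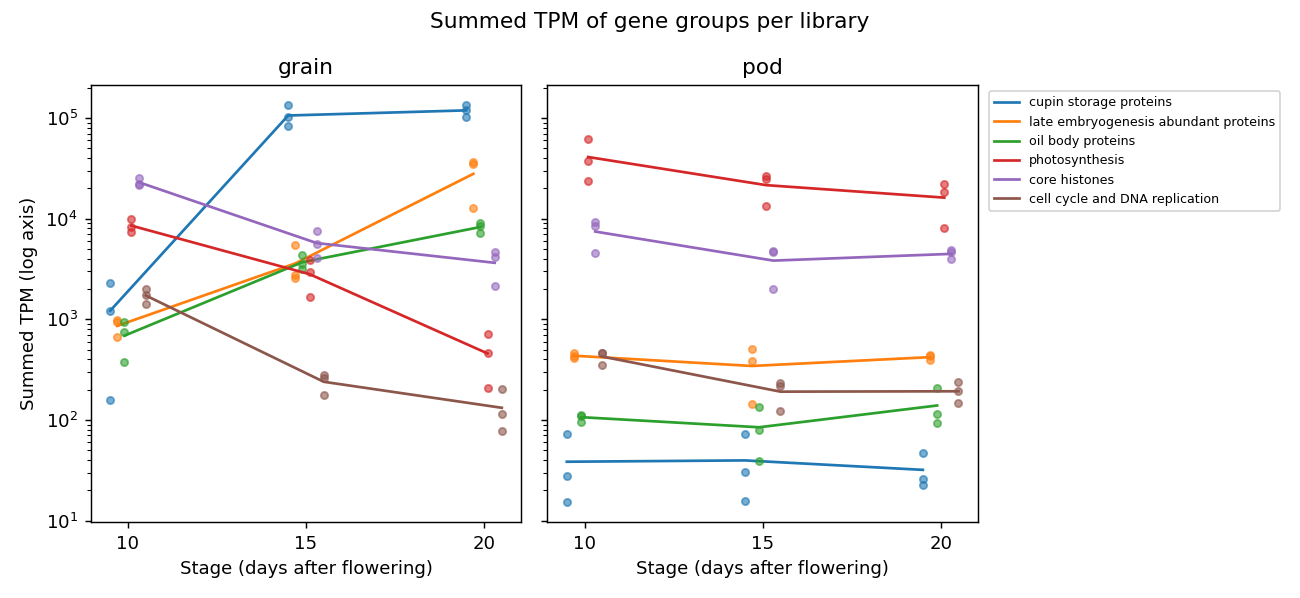
Summed TPM (log axis) of 6 gene groups against the stage in days after flowering, in grain (left) and pod (right). Each point is 1 library, shifted sideways for visibility, and lines join group means of 3 libraries; in grain the cupin mean went from 1214 to 119098 TPM and the photosynthesis mean from 8516 to 457 TPM, while pod cupins stayed between 15.2 and 72.6 TPM.

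The intermediate stage divided these changes in grain. From 10 to 15 DAF all 8 cupin genes rose, to a sum of 105906 ± 25914 TPM. At the same time 14 of 23 LEA genes rose and 1 fell (16 and 0 after median-ratio scaling; 14 and 1 adjusted over the list alone). Cell cycle and replication genes fell in 43 of 49 cases. The camera test gave adjusted p = 2.61e-30, 6.56e-22 and 1.46e-11 for these lists. It gave adjusted p = 0.0326, 0.0350 and 0.360 with an estimated correlation, so the cell cycle call was lost. The Rossmann-fold gene Phvul.003G091300 reached 1663 ± 1012 TPM and the cupin Phvul.007G059750 went from 55.7 ± 48.6 to 8525 ± 2888 TPM. The defensin-like PDF2.4 (Phvul.002G278500) fell from 213 ± 226 to 0.881 ± 0.504 TPM and a MATE transporter (Phvul.003G064300) from 94.3 ± 35.8 to 0.368 ± 0.274 TPM. In total 379 genes were higher and 6842 lower with a median of -0.75 over all genes. These became 1108 and 2011 with a median of -0.08 after median-ratio scaling, and 1315 and 1842 with the 50 most abundant genes left out.

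From 15 to 20 DAF, 16 of 23 LEA genes rose and 1 fell (19 and 1 adjusted over the list alone), and 42 of 77 photosynthesis genes fell (47 adjusted over the list alone). The LEA sum was 36166, 34625 and 12832 TPM in replicates 1, 2 and 3 at 20 DAF, the last being the library closest to 15 DAF, against 2549 to 5492 TPM at 15 DAF. The camera test gave adjusted p = 4.03e-37 for LEA, and 0.0120 with an estimated correlation. It gave 1.08e-23 for photosynthesis, with adjusted p = 0.375 with an estimated correlation. A seed maturation protein (Phvul.007G057900) went from 3.30 ± 1.84 to 568 ± 600 TPM. A lipid-transfer or 2S albumin family gene (Phvul.008G198500) fell from 75.5 ± 16.5 to 0.721 ± 0.565 TPM (log2 difference -5.50, SE 0.31, adjusted p = 9.41e-09). PDF2.3 rose by a log2 of 8.01 and the cell wall protein precursor Phvul.005G106200 fell by 5.40. Fitted on these 6 libraries alone, PDF2.3, Phvul.007G057900 and Phvul.005G106200 had adjusted p of 0.0606, 0.0790 and 0.0838. In total 178 genes were higher and 1002 lower with a median of -0.29, against 519 and 930 with a median of -0.04 after median-ratio scaling. A total of 258 genes passed in the fit of these 6 libraries alone. The total of 1180 became 424 without grain 15 DAF replicate 2, 537 without grain 15 DAF replicate 3 and 398 without grain 20 DAF replicate 1.

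In pods, antenna, histone and wall-loosening transcripts fell from 10 to 20 DAF. Of 34 light-harvesting genes 22 fell and 0 rose, and their sum went from 25044 ± 11152 to 7646 ± 3838 TPM. LHCB3 (Phvul.005G085800) fell from 936 ± 385 to 52.1 ± 30.8 TPM (log2 difference -4.28, SE 0.54, adjusted p = 3.53e-05) and an LHCB1 gene (Phvul.004G091988) from 132 ± 105 to 0.0253 ± 0.0439 TPM. In the separate photosynthesis list 17 of 77 genes fell, or 28 after median-ratio scaling and 26 adjusted over the list alone. With 17 falls against 22, that list cannot hold all the light-harvesting genes, and the overlap of both lists was not computed. Of 46 core histone genes 27 fell, with Phvul.003G073800 going from 104 ± 45.3 to 7.88 ± 7.90 TPM. Of 49 cell cycle genes 9 fell, including cyclin CYCD3;2 (Phvul.009G067600) from 70.8 ± 34.0 to 9.10 ± 6.66 TPM. Of 83 genes for cell wall loosening and pectin breakdown 30 fell and 6 rose (31 and 6 adjusted over the list alone). The expansin EXP1 (Phvul.008G037500) fell from 413 ± 239 to 5.04 ± 4.95 TPM, and the expansin-like EXLB1 (Phvul.003G224800) rose from 0.377 ± 0.654 to 15.5 ± 11.3 TPM. Of 27 genes for nitrogen assimilation and amino acid transport 8 rose and 0 fell (9 and 1 adjusted over the list alone), among them ureide permease 2 (Phvul.003G042700), a carrier of the nitrogen-rich ureides, from 0.338 ± 0.218 to 34.7 ± 36.6 TPM. Of 54 WRKY transcription factors 8 rose, also 8 adjusted over the list alone, with WRKY75 (Phvul.001G088200) going from 8.77 ± 10.5 to 232 ± 98.8 TPM. The camera test gave adjusted p from 7.46e-21 for light-harvesting proteins to 0.0149 for WRKY factors over these 7 lists. It gave adjusted p = 0.579 to 0.772 with an estimated correlation, so none was kept there. The WRKY adjusted p was also 0.215 without pod 20 DAF replicate 2, 0.126 without pod 10 DAF c3 and 0.0940 on the pod libraries of both stages alone.

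Among single pod genes, the lipoxygenases Phvul.010G134900 and Phvul.005G156900 fell from 301 ± 167 to 1.62 ± 1.36 TPM and from 475 ± 256 to 4.77 ± 3.57 TPM. The lipid-transfer family genes Phvul.001G050300 and Phvul.003G169100 fell from 266 ± 243 to 1.15 ± 0.881 TPM and from 427 ± 342 to 3.67 ± 3.77 TPM. The membrane protein DMP2 (Phvul.006G158800) rose from 1.90 ± 2.49 to 241 ± 221 TPM. An AP2-type transcription factor (Phvul.002G281300) rose from 0.546 ± 0.409 to 55.7 ± 13.0 TPM, and a gene described as DXR, an enzyme of plastid isoprenoid synthesis (Phvul.010G023000), from 0.139 ± 0.241 to 55.7 ± 50.1 TPM. LOX2 (Phvul.011G056500), a lipoxygenase, rose from 23.2 ± 17.3 to 398 ± 232 TPM. The basic chitinase Phvul.009G116500, of a defence-related family, was at 201, 4767 and 1698 TPM in the 3 libraries at 20 DAF and 31.2 ± 25.6 TPM at 10 DAF. Its neighbour Phvul.009G116600 was at 8.41, 853 and 376 TPM against 3.34 ± 2.13 TPM. The cytochrome P450 CYP93D1 (Phvul.003G051700) was at 13.4, 2297 and 64.5 TPM at 20 DAF and 0.424 ± 0.368 TPM at 10 DAF. Pod 20 DAF replicate 2 held the highest value of each of these 3 genes. In all, 1069 genes were higher and 1335 lower, with a median of 0.10 over all genes and -0.02 after median-ratio scaling. Fitted on the pod libraries of both stages alone, 156 genes were higher and 238 lower. There, adjusted p for CYP93D1, both chitinases, Phvul.003G073800, CYCD3;2, ureide permease 2, EXLB1, WRKY75 and LOX2 was 0.0532 to 0.174. The total of 2404 became 1517 without pod 10 DAF c1, and without c2 the split became 1517 higher and 1487 lower.

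**Figure D2:**
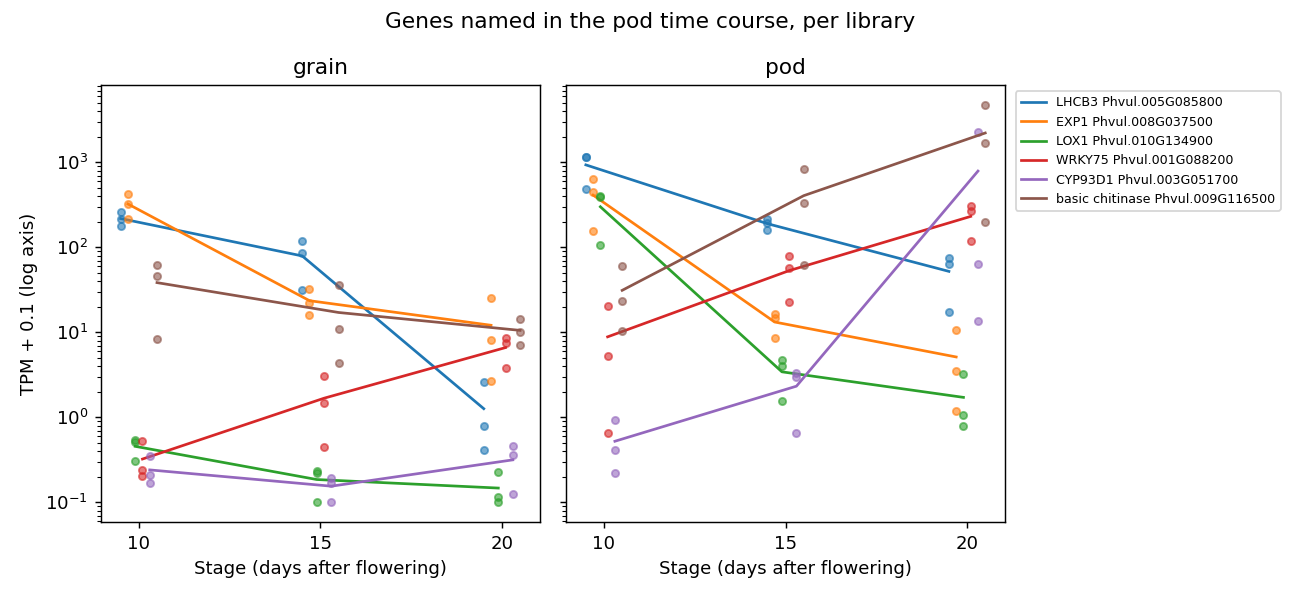
TPM plus 0.1 (log axis) of 6 genes named in the pod time course against the stage in days after flowering, in grain (left) and pod (right). Each point is 1 library, shifted sideways for visibility, and lines join group means of 3 libraries; CYP93D1 stood at 13.4, 64.5 and 2297 TPM in the pod libraries at 20 DAF, and LHCB3 fell in pods from a mean of 936 to 52.1 TPM.

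In pods at 15 against 10 DAF, of 15 genes for secondary wall cellulose and xylan 5 rose and 1 fell, including the xylan gene IRX8 (Phvul.005G091200) from 10.3 ± 4.04 to 42.5 ± 21.6 TPM. The secondary wall factor SND2 (Phvul.005G100100) rose from 5.96 ± 3.41 to 38.4 ± 20.1 TPM. Of 83 wall-loosening genes 24 fell and 1 rose, or 33 and 1 adjusted over the list alone and 23 and 0 after median-ratio scaling. Of 46 core histone genes 19 fell. List sums of the libraries overlapped between the stages for secondary walls (277 to 826 TPM at 15 DAF, 196 to 336 TPM at 10 DAF) and core histones (1992 to 4786 and 4556 to 9264 TPM), but not for wall loosening (1444 to 3101 and 4677 to 10046 TPM). Pod 15 DAF replicate 3 was the lowest at 15 DAF in each. Its column summed to 436072 TPM, against 988376 and 895916 TPM in replicates 1 and 2, so its low list sums need not reflect the tissue. The overlap for secondary walls came from that library alone, as replicates 1 and 2 were at 826 and 645 TPM. The camera test gave adjusted p = 0.000254, 2.66e-07 and 1.38e-11 for these lists, each with adjusted p = 0.937 with an estimated correlation. A Kunitz inhibitor (Phvul.004G129600) fell from 182 ± 187 to 0.796 ± 0.654 TPM and the lipoxygenase Phvul.010G134900 from 301 ± 167 to 3.34 ± 1.68 TPM. DMP2 (Phvul.006G158800) rose to 103 ± 123 TPM, with an adjusted p of 0.0120 that became 0.0592 without pod 15 DAF replicate 1. The gene for subunit 9 of the mitochondrial ATPase (Phvul.005G088454) was at 136, 607 and 1715 TPM at 15 DAF against 30.6 ± 30.9 TPM at 10 DAF, with an adjusted p of 0.0226. That value became 0.0930 and 0.0857 without pod 10 DAF c1 or c3, 0.0694 and 0.105 without pod 15 DAF replicate 2 or 3, and 0.0549 with no filter. In total 299 genes were higher and 1043 lower with a median of -0.16, against 586 and 831 with a median of -0.02 after median-ratio scaling. The split was 914 and 660 with the 50 most abundant genes left out, and 1081 and 630 after rescaling each column to the same sum. Fitted on these 6 libraries alone, limma called 0 genes, with 2577 at an unadjusted p under 0.05, and adjusted p for the 6 genes named here was 0.0740 to 0.232. The total of 1342 became 620 without pod 10 DAF c1 and 778 without pod 15 DAF replicate 2, and without pod 15 DAF replicate 3 the split turned to 739 higher and 591 lower.

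From 15 to 20 DAF in pods, 4 of 54 WRKY factors rose (15 adjusted over the list alone, 1 after median-ratio scaling) and 2 of 34 light-harvesting genes fell (5 after median-ratio scaling). The camera test gave adjusted p = 0.00107 and 2.42e-14, against adjusted p = 0.769 and 0.621 with an estimated correlation, and the WRKY value was 0.0995 without pod 20 DAF replicate 2. A MtN21-type transporter (Phvul.008G164000) rose from 0.206 ± 0.0968 to 23.9 ± 10.9 TPM and a family 17 glycosyl hydrolase (Phvul.008G213400) fell from 63.6 ± 23.1 to 6.64 ± 9.70 TPM. CYP93D1 rose by a log2 of 5.45 (SE 1.06), or 3.38 without pod 20 DAF replicate 2, and its adjusted p of 0.0113 became 0.0634 without pod 15 DAF replicate 3. An acid phosphatase (Phvul.010G144300) went from 958 ± 1341 to 38.3 ± 47.1 TPM, with an adjusted p of 0.0133 that became 0.0549 without pod 15 DAF replicate 2 and 0.0504 without pod 20 DAF replicate 1. In total 221 genes were higher and 103 lower with a median of 0.27. That direction turned, to 160 and 374 with a median of 0 after median-ratio scaling, 147 and 406 with the 50 most abundant genes left out, and 172 and 457 after rescaling each column to the same sum. Fitted on these 6 libraries alone, limma called 0 genes, with 1588 at an unadjusted p under 0.05. Adjusted p for the 4 genes named here was 0.303 to 0.577 there, and a pseudocount of 0.1 TPM gave 92 higher and 83 lower genes. The total of 324 became 993 without pod 15 DAF replicate 1, 184 without pod 15 DAF replicate 2 and 214 without pod 20 DAF replicate 2, and without pod 15 DAF replicate 3 the split was 79 and 183.

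At 10 DAF, grain held more transcripts of seed regulators and dividing cells than pod, and pod more of photosynthesis and phloem. Of 10 seed maturation regulators 9 were higher in grain. NF-YB6 (Phvul.003G087000), a relative of the embryo regulator LEC1, was at 619 ± 149 TPM in grain and 0.254 ± 0.178 TPM in pod (log2 difference 8.93, SE 0.40, adjusted p = 6.45e-12). ABI3 (Phvul.008G122100), a regulator of seed maturation, was at 122 ± 49.2 and 0.152 ± 0.223 TPM. Of 17 gibberellin genes 13 were higher and 2 lower in grain, with the same counts adjusted over the list alone. The sum over all 39 matched gibberellin genes was 1438 ± 210 TPM in grain and 1677 ± 179 TPM in pod. The synthesis gene GA20OX2 (Phvul.010G087500) was at 149 ± 28.7 TPM against 0.222 ± 0.331 TPM, and a gibberellin-regulated protein (Phvul.009G181500) was lower in grain, at 45.9 ± 21.9 against 1488 ± 246 TPM. Both lists passed the camera test with a preset correlation, at adjusted p = 1.48e-08 and 2.18e-05, and with an estimated one, at 0.00258 and 0.0327. Of 6 flavonoid genes 5 were higher in grain and 1 lower, 5 and 1 also adjusted over the list alone. They included the tannin genes DFR (Phvul.001G012700) at 233 ± 230 against 0.525 ± 0.481 TPM and BAN (Phvul.002G218700) at 330 ± 236 against 0.787 ± 0.521 TPM. Cell cycle genes were higher in grain in 37 of 49 cases and lower in 2, core histones higher in 39 of 46 and lower in 1, and ribosomal protein genes higher in 161 of 289 and lower in 1. These 4 lists had camera adjusted p from 6.55e-12 for the cell cycle to 0.00555 for flavonoids, and adjusted p = 0.44 to 0.571 with an estimated correlation. Pod was higher in 51 of 77 photosynthesis genes (53 adjusted over the list alone), 31 of 34 light-harvesting genes and 9 of 15 phloem protein genes (9 adjusted over the list alone), with 0 lower. It was higher in 18 of 39 NAC factors with 4 lower (18 and 4 adjusted over the list alone). Camera adjusted p went from 3.19e-11 for light-harvesting proteins to 0.00563 for NAC factors, and adjusted p was 0.495 to 0.620 with an estimated correlation. The phloem lectin PP2-B10 (Phvul.001G013300) was at 98.2 ± 38.7 TPM in pod and 1.51 ± 1.04 TPM in grain, and NAC047 (Phvul.001G100200) at 27.6 ± 17.7 and 0.395 ± 0.0671 TPM.

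The largest differences towards grain at 10 DAF included RAS1 (Phvul.008G097900), at 4143 ± 1407 against 4.59 ± 1.00 TPM, and alcohol dehydrogenase 1 (Phvul.001G064000), at 1661 ± 801 against 1.02 ± 1.22 TPM. They also included annexin 8 (Phvul.005G030100), at 1173 ± 202 against 0.948 ± 0.683 TPM, and the homeobox factor HB33 (Phvul.006G217500), at 555 ± 288 against 0.0380 ± 0.0658 TPM. The largest towards pod included the acid phosphatase Phvul.010G144300, at 1610 ± 703 against 0.408 ± 0.258 TPM, and the lignin pathway enzyme CCoAOMT1 (Phvul.003G242350), at 254 ± 119 against 0.160 ± 0.161 TPM. They also included the auxin repressor IAA7 (Phvul.007G176600), at 416 ± 261 against 2.92 ± 3.32 TPM, and a beta-amylase (Phvul.011G107700), at 388 ± 185 against 2.29 ± 0.859 TPM. In all, 3528 genes were higher in grain and 3339 in pod, with a median of 0.02, and after median-ratio scaling 3267 and 3357.

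At 15 DAF the seed maturation regulators were higher in grain in 8 of 10 cases. Photosynthesis genes were higher in pod in 64 of 77 (66 adjusted over the list alone) and secondary wall genes in 12 of 15, with 0 lower in pod as deposited and 2 of the wall genes lower after median-ratio scaling. Camera adjusted p was 2.70e-13, 2.39e-10 and 0.00456, and adjusted p = 0.000239, 0.432 and 0.554 with an estimated correlation, so only the seed regulators were kept of these 3 lists. The cupin Phvul.007G059725 was at 13851 ± 1113 TPM in grain and 2.06 ± 2.06 TPM in pod. Rubisco activase (Phvul.001G234300), which keeps the carbon-fixing enzyme active, was at 2.25 ± 0.376 and 781 ± 288 TPM (log2 difference -7.84, SE 0.46, adjusted p = 2.23e-10). In total 1773 genes were higher and 5979 lower in grain with a median of -0.55, against 2880 and 3672 with a median of -0.04 after median-ratio scaling and 2692 and 4689 with the 50 most abundant genes left out. The counts depended on pod 15 DAF replicate 3, whose column summed to 436072 TPM. Rescaling each column to the same sum gave 1621 and 8112 with a median of -0.82. Without that library they were 1506 and 8111 with a median of -0.83.

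At 20 DAF, grain stood apart from pod in cupin, LEA and oil body genes. All 8 cupin genes were higher in grain, with a median log2 difference of 11.56, and 19 of 23 LEA genes were higher and 3 lower (19 and 4 adjusted over the list alone, 19 and 0 after median-ratio scaling). Oil body genes were higher in 6 of 12 cases and lower in 1 (6 and 1 adjusted over the list alone), and abscisic acid genes higher in 4 of 6 (4 adjusted over the list alone). In a wider abscisic acid list of 37 genes, worded after the descriptions were read, 8 were higher and 21 lower, or 12 and 14 after median-ratio scaling. Its median of -1.40 and mean of -0.48 were negative, while the camera test pointed upwards without passing, at adjusted p = 0.0507 and, with an estimated correlation, 0.730. That value passed with no filter (0.00619), on these 6 libraries alone (0.0404) and without grain replicate 2 (0.0443) or pod replicate 1 (0.0318). Summed over all 50 matched genes, this list was at 1763 ± 189 TPM in grain and 1756 ± 559 TPM in pod, but at 3344 ± 564 and 1218 ± 362 after median-ratio scaling. Seed maturation regulators were higher in 7 of 10 cases, and protease inhibitors higher in 8 of 20 and lower in 3 (8 and 3 adjusted over the list alone). Oleosin 1 (Phvul.007G138300) was at 3890 ± 553 TPM against 1.44 ± 1.38 TPM in pod. The phytocystatin CYS2 (Phvul.001G264400), an inhibitor of cysteine proteases, was at 2056 ± 71.5 against 1.00 ± 0.521 TPM, and LEA4-5 at 11946 ± 6540 against 3.22 ± 1.77 TPM. The lectin-like Phvul.004G158300 was the most abundant of the genes named here, at 97123 ± 20740 against 31.9 ± 17.4 TPM. The 6 lists other than this wider one had camera adjusted p from 7.29e-32 for LEA to 9.62e-08 for oil body proteins, and all 6 passed with an estimated correlation, at adjusted p = 8.41e-05 to 0.0328. Photosynthesis genes were higher in pod in 69 of 77 cases (70 adjusted over the list alone; camera adjusted p = 6.73e-10, adjusted p = 0.490 with an estimated correlation). Phloem proteins were higher in pod in 14 of 15 (14 adjusted over the list alone, 8 after median-ratio scaling; camera adjusted p = 0.00404, adjusted p = 0.516 with an estimated correlation). Rubisco activase was at 1256 ± 458 TPM in pod and 0.953 ± 0.543 TPM in grain. Phosphoribulokinase (Phvul.002G133100), another enzyme of carbon fixation, was at 322 ± 149 and 0.0660 ± 0.0185 TPM, and the plastid aldolase FBA2 (Phvul.011G039100) at 2691 ± 798 and 2.65 ± 1.77 TPM. A terpene synthase (Phvul.005G135000) was at 617 ± 305 TPM in pod against 0.0747 ± 0.0216 TPM and the phloem lectin PP2-B15 (Phvul.006G087800) at 130 ± 146 against 0.0480 ± 0.0831 TPM. In total 1242 genes were higher and 11260 lower in grain, with a median of -1.18. These became 2794 and 3984 with a median of -0.07 after median-ratio scaling, and 2209 and 5672 with the 50 most abundant genes left out. Of all genes, 763 were higher in grain at all 3 stages, against 19.7 for independent lists of these sizes, and 2648 were higher in pod at all 3, against 570. After median-ratio scaling these counts were 1244, against 66.6, and 2033, against 125. The same tissues were compared each time and in 1 fit, so independence was ruled out beforehand and the excess tests nothing. The side on which a gene was higher switched between 10 and 20 DAF for 597 genes, or 138 after median-ratio scaling.

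The change from 10 to 20 DAF itself differed between the tissues. LEA genes changed more upwards in grain than in pod in 19 of 23 cases and less in 1 (19 and 1 adjusted over the list alone, 19 and 0 after median-ratio scaling). All 8 cupin genes did so, and oil body genes did so in 4 of 12 cases with 2 the other way (4 and 1 adjusted over the list alone, 6 and 0 after median-ratio scaling). Genes for raffinose family sugars went that way in 4 of 7 cases and the other in 1 (4 and 1 adjusted over the list alone). These 4 lists passed the camera test at adjusted p = 1.57e-36, 1.25e-23, 8.58e-07 and 1.30e-06, and with an estimated correlation at 0.0129 to 0.0247. LEA4-5 changed by a log2 of 10.42 more in grain (SE 1.02, adjusted p = 1.34e-06). The Kunitz inhibitor Phvul.004G129600 went from 3.00 ± 0.779 to 127 ± 121 TPM in grain and from 182 ± 187 to 2.89 ± 4.03 TPM in pod, a difference of 9.97. The oleosin Phvul.008G144500 rose in grain and fell from 29.5 ± 9.92 to 1.92 ± 0.718 TPM in pod, a difference of 7.50. In the other direction, the auxin glucosyltransferase IAGLU (Phvul.001G265400) went from 146 ± 101 to 0.237 ± 0.271 TPM in grain and from 5.54 ± 1.59 to 27.7 ± 6.51 TPM in pod, a difference of -8.79. The MATE transporter Phvul.003G064300 differed by -8.73, ureide permease 2 (Phvul.003G042700) by -4.96 and LOX2 (Phvul.011G056500) by -6.43. The MATE gene stood at 273 TPM in pod 20 DAF replicate 2, against at most 29.1 TPM in any other pod library. Ribosomal protein genes changed more downwards in grain in 258 of 289 cases (56, with 3 the other way, after median-ratio scaling), cell cycle genes in 38 of 49 (20 after median-ratio scaling) and photosynthesis genes in 56 of 77 with 2 the other way (57 and 2 adjusted over the list alone, 26 and 1 after median-ratio scaling). Camera adjusted p was 4.88e-09, 0.00376 and 0.00678 for these lists, and adjusted p = 0.730, 0.766 and 0.821 with an estimated correlation. The photosynthesis value was 0.111 without pod 10 DAF c2 and the cell cycle value 0.497 with a pseudocount of 0.1 TPM. Light-harvesting genes went more downwards in grain in 15 of 34 cases and less in 7, with a median of -1.0 and a mean of -0.87, while their camera test pointed upwards at adjusted p = 0.0130. That value was 0.821 with an estimated correlation, 0.991 after median-ratio scaling, and 0.709 with the 50 most abundant genes left out. It was 0.803 with a pseudocount of 0.1 TPM, 0.0522 with no filter, 0.164 without pod 10 DAF c3, 0.173 without pod 20 DAF replicate 2 and 0.0676 without grain 20 DAF replicate 3. In total 732 genes changed more upwards and 10494 more downwards in grain than in pod with a median of -1.25. These became 1788 and 2520 with a median of -0.13 after median-ratio scaling, and 1382 and 3442 with the 50 most abundant genes left out.

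**Figure D3:**
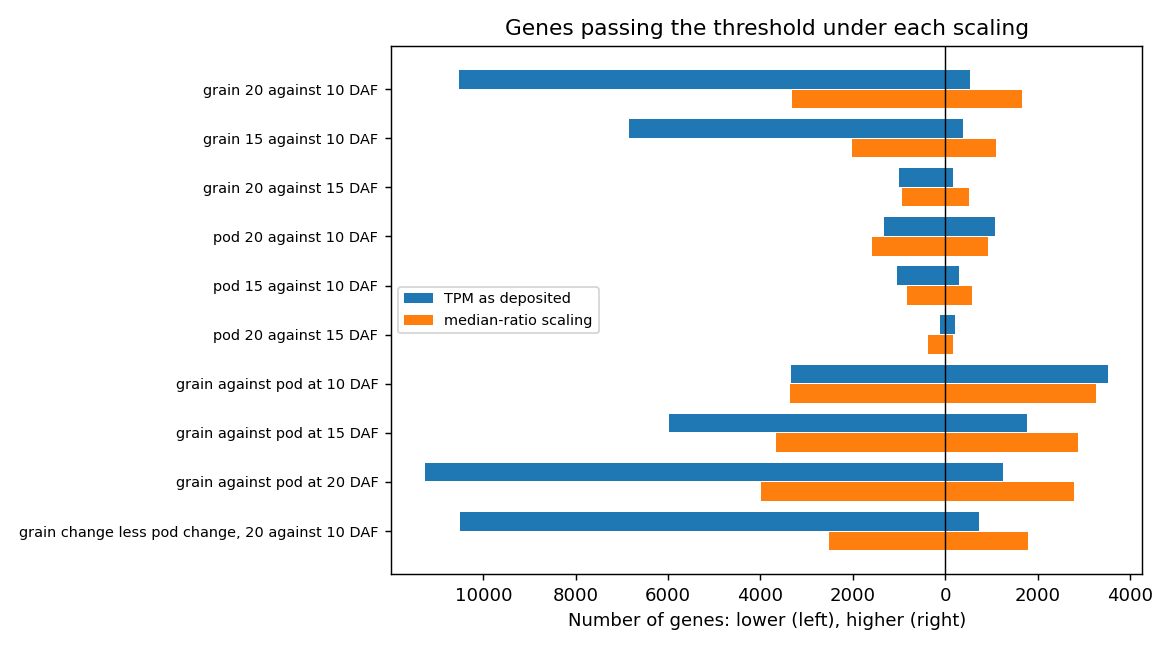
Number of genes passing the threshold in each comparison, lower to the left of 0 and higher to the right, for TPM as deposited and after median-ratio scaling. In grain at 20 against 10 DAF 530 genes were higher and 10516 lower as deposited, and 1665 higher and 3313 lower after scaling; for grain against pod at 10 DAF the sides were 3528 and 3339, and 3267 and 3357.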

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

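The tests of abundant transcripts and of column sums in this part were chosen after the result had been seen, and the counts of other splits before it.

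The test of the difference between tissues singled out the change from 10 to 20 DAF, which differed between grain and pod for 11226 genes. That count was 4308 after median-ratio scaling and 4824 with the 50 most abundant genes left out. By the same test, the lists for photosynthesis (camera adjusted p = 0.00678), light-harvesting proteins (0.0130), cell cycle and replication (0.00376) and lipoxygenases (3.80e-06) differed between the tissues. With an estimated correlation these adjusted p were 0.821, 0.821, 0.766 and 0.151, and the lipoxygenases had a median of -0.02 beside a mean of 0.78 and a test upwards. The light-harvesting test pointed upwards too, against a median of -1.0 and a mean of -0.87, and its adjusted p was 0.0522 to 0.991 with no filter, a pseudocount of 0.1 TPM, the 50 most abundant genes left out or median-ratio scaling, and 0.0676, 0.164 and 0.173 without grain 20 DAF replicate 3, pod 10 DAF c3 or pod 20 DAF replicate 2. The cell cycle value was 0.497 with that pseudocount and the photosynthesis value 0.111 without pod 10 DAF c2. The single genes so singled out were LHCB3 (Phvul.005G085800, difference of log2 changes -2.50), LEA4-5 (Phvul.001G142000, 10.42), the Kunitz inhibitor Phvul.004G129600 (9.97), the auxin glucosyltransferase IAGLU (Phvul.001G265400, -8.79) and the MATE transporter Phvul.003G064300 (-8.73). The MATE value draws in part on pod 20 DAF replicate 2, at 273 TPM against at most 29.1 TPM in any other pod library.

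Stage labels were redrawn within each tissue for the difference between tissues, in 100 of 200 possible splits with the real one included, and 1 of 100, the real one, gave as many as 11226 genes. That share is under 0.05 for the stage labels of both tissues at once, with a highest other count of 10233. A change in grain alone can give such a share, so it cannot exclude chance for the difference between the tissues. Splits that mixed the grain stages gave at most 343 genes, so the count points to the structure of the grain libraries. With the real one, 11 splits kept the grain stages, too few for a share under 0.05 for the pod stages alone, and the other 10 gave 7576 to 10233 genes. For each comparison of 3 with 3 libraries, 10 splits are too few for a share under 0.05, and 1 of 10, the real one, gave as many genes. The real count and the highest other were 11046 and 8 for grain at 20 against 10 DAF, 7221 and 1 at 15 against 10 DAF, and 1180 and 15 at 20 against 15 DAF. They were 2404 and 25, 1342 and 958, and 324 and 27 for the same comparisons in pods, and 6867 and 0, 7752 and 1, and 12502 and 1 for grain against pod at 10, 15 and 20 DAF. A highest other count of 958 beside 1342 for pods at 15 against 10 DAF came from the split that exchanged pod 10 DAF c2 and pod 15 DAF replicate 3, which is the library that c2 correlated with best (r = 0.938).

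The fall of 10516 genes in grain from 10 to 20 DAF was weighed against features of the values. Unequal column sums are argued against as its cause, since rescaling each column to the same sum left the median log2 change of all genes at -1.09. The large share of a few abundant transcripts, by which every other TPM value must drop, could account for most of it, since leaving out the 50 most abundant genes brought the median to -0.24. That scaling still gave 4037 lower and 1425 higher genes, so part of the excess of lower genes stays open. The stage of the grain itself remains an open explanation that TPM cannot test, because the total amount of RNA per grain was not measured in these values.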

How the results depend on the processing

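Alternatives were planned, except rescaling each column to the same sum and leaving out libraries in the list tests, which were chosen after seeing the data. Of 126 gene differences taken by the rules, each past the threshold, 103 stayed past it under every alternative run, none changed sign, and the others are given with their comparisons. With the 50 most abundant genes left out 110 of them could be run, and with the replicate block 61. They were chosen in these same data as large or abundant called genes, so that share does not describe called genes in general. Of 62 list sums, 36 moved by more than 1 SD under median-ratio scaling. The depth of the libraries is unknown, so no limit was computed from it. For leaving out libraries or abundant genes the setting shows the cause, and otherwise the cause was not tested. Fewer libraries need not be the cause in fits on only the groups compared. There, genes at a limma unadjusted p under 0.05 went from 13648 to 14728 for grain at 20 against 10 DAF. For pods at 15 against 10 DAF they went from 4226 to 2577. The main fit pools the spread over 6 groups, so its pod p-values rest in part on the grain libraries and may be too small.

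After median-ratio scaling, counts of changed genes were 4978 in grain at 20 against 10 DAF, 3119 at 15 against 10 DAF, 534 in pods at 20 against 15 DAF, 6778 for grain against pod at 20 DAF and 4308 for the difference between tissues, where 13 lists passed in place of 22; 1244 genes were higher in grain at all 3 stages. With the 50 most abundant genes left out, counts were 5462, 3157 and, for grain at 20 against 15 DAF, 1879, then 553, 7881 and 4824 as above, with 12 lists. In fits on only the groups compared, counts were 258 for grain at 20 against 15 DAF, 394 for pods at 20 against 10 DAF, and 0 by limma for pods at 15 against 10 and at 20 against 15 DAF (2577 and 1588 at an unadjusted p under 0.05). A pseudocount of 0.1 TPM gave 175 for pods at 20 against 15 DAF, and rescaling each column to the same sum 629 there and 2279 for grain at 20 against 15 DAF.

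With an estimated correlation, lists passing were 5 in place of 23 for grain at 20 against 10 DAF, 0 in place of 15 for pods, 2 in place of 24 and 7 in place of 23 for grain against pod at 10 and 20 DAF, and 5 in place of 22 for the difference between tissues.

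With a library left out, counts ranged from 398 to 1461 in place of 1180 for grain at 20 against 15 DAF, and in pods from 1517 to 3004 in place of 2404 at 20 against 10 DAF, 620 to 1716 in place of 1342 at 15 against 10 DAF, and 184 to 993 in place of 324 at 20 against 15 DAF.

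The labels name no shared source for same-numbered libraries, so they were not treated as pairs. The correlation of their deviations between groups was over 0.1 in 9 of 30 pairs (-0.165 to 0.237), which does not speak against pairing. Its median was 0.0042, against -0.0185 for pairs of unlike number. As a hint from the data towards pairing, 10 of 15 libraries correlated best with their own number, where 5 would be expected with no pairing. With the replicate block, run without pod 10 DAF, counts were 11123, 7303 and 1066 for the grain comparisons in the order above, 471 for pods at 20 against 15 DAF, and 7836 and 12586 for grain against pod at 15 and 20 DAF. The planned block of 5 levels for comparisons with pod 10 DAF was not run, because those columns carry no replicate number.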

Other observations

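The tests of the cupin levels, of grain tissue and of a swap in this part were chosen after the result had been seen; that of a swap replaced a count chosen before it, of libraries that correlated best with another group (2 of the other 17), which decided nothing since neither matched pod 20 DAF.

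Lipoxygenase genes were split by tissue and stage. In grain, the LOX1 genes Phvul.005G156700 and Phvul.005G157000 rose from 64.9 ± 56.7 to 909 ± 192 TPM and from 10.7 ± 6.43 to 1303 ± 274 TPM between 10 and 20 DAF (limma adjusted p = 3.99e-06 and 2.41e-09), and were below 1 TPM in pods on average at every stage. Of 18 lipoxygenase genes 2 rose and 5 fell in grain, with a median of -0.13, a mean of 0.00047 and a camera test upwards at adjusted p = 0.000675. That value became 0.217 after median-ratio scaling, 0.106 with the 50 most abundant genes left out and 0.40 with an estimated correlation. In pods 3 rose and 4 fell (camera adjusted p = 0.0994, but 0.0150 with no filter and 0.0323 without pod 10 DAF c2). At 20 DAF 2 were higher and 10 lower in grain than in pod, with a median of -1.19 and a camera test upwards at adjusted p = 0.409.

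Aquaporin genes, which code for water channels, were likewise divided. At 10 DAF, 7 of 22 were higher and 9 lower in grain than in pod (camera adjusted p = 0.771), with TIP3;1 (Phvul.004G136000), a channel of seed storage vacuoles, at 442 ± 241 against 1.75 ± 1.89 TPM and TIP1;1 (Phvul.001G181100) at 334 ± 40.5 against 4010 ± 1813 TPM. The plasma membrane channel gene Phvul.002G290400 fell from 10 to 20 DAF in both tissues, from 610 ± 194 to 54.3 ± 34.4 TPM in grain and from 581 ± 520 to 12.2 ± 5.41 TPM in pod. TIP2;1 (Phvul.010G147100) fell in pods by a log2 of 4.96 (SE 0.61), with an adjusted p of 0.0589 on the pod libraries of both stages alone. Over pods 1 of 22 rose and 5 fell (camera adjusted p = 0.00194, adjusted p = 0.579 with an estimated correlation). Of 29 MADS-box genes, a family of flower and fruit regulators, 9 were higher and 10 lower in grain at 10 DAF, also 9 and 10 adjusted over the list alone (camera adjusted p = 0.912, median -0.19 and mean 0.12). STK (Phvul.005G000900), an ovule and seed regulator, was at 120 ± 48.5 against 3.20 ± 5.05 TPM, and FUL (Phvul.009G203400), a fruit wall regulator, at 0.142 ± 0.0860 against 62.5 ± 11.2 TPM.

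Cupin storage transcripts were listed in every pod library, at 15.2 to 72.6 TPM in sum. Grain of the same stage carried into the pod samples is argued against, since the pod sum at 20 DAF was 0.830 times that at 10 DAF while the grain sum was 98.1 times as high. A constant share of grain reads in every pod library could give low ratios, but its test does not decide this. The median pod to grain ratio of the cupins was 0.0514%, and 0% of 88 genes with at least 1000 TPM in grain lay under 0.2 times that ratio. Expression in the pod can only raise such a ratio, and the cupins were among the 88 genes, so the test could hardly fail. Oleosin 1 (Phvul.007G138300), TIP3;1 (Phvul.004G136000) and LEA4-5 (Phvul.001G142000) were near the cupin ratio, at 0.0629%, 0.0745% and 0.0794%. Others of the 88 genes reached up to 1346.5%. Low pod levels of such seed genes may include grain reads, which these values do not decide. The cupin sum was also uneven, at 15.5, 30.5 and 72.6 TPM in pod 15 DAF replicates 1, 2 and 3. Low expression in the pod itself would give such values too and was not tested separately. No biological explanation was tested, since the labels give no group that would bear on it.

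Pod 20 DAF replicate 2 stood apart from the other pod libraries: with thresholds chosen after it was seen to do so, 130 genes had at least 20 TPM there and at least 8 times the highest other pod value, against 15 in the pod library with the next highest count, and they included, named after their values were seen, CYP93D1 (Phvul.003G051700) at 2297 TPM, a chalcone isomerase (Phvul.007G008600) at 1487 TPM, the ethylene synthesis gene ACO4 (Phvul.002G326600) at 1025 TPM and ERF1 (Phvul.007G273000) at 408 TPM. Grain tissue in that sample is argued against, since its summed cupin level of 26.1 TPM lay within the 15.2 to 72.6 TPM of the other 8 pod libraries. A swap with another library of the series is argued against, since 0 libraries of the other 5 groups correlated best with a pod 20 DAF library, as a partner would. A single wrong label or a sample from outside the series stays open, as replicate 2 correlated across genes at r = 0.905 and 0.922 with the other pod 20 DAF libraries and at up to 0.895 with another group, and no biological explanation was tested, as the labels give no group that separates this library.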
